A study of Mus musculus with 59 samples.

How the data were processed

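RNA was measured in the prefrontal cortex of 59 mice, 30 heterozygous for a Dyrk1a mutation and 29 wild type, from strand-specific libraries of polyadenylated RNA. Per the submitters' processing notes, Salmon 0.11.2, R 3.6.0 and DESeq2 1.19.11 were used with the GRCm38 build, with no role or order given for each. The authors deposited 1 table of normalized values, which is a signal per gene and library: counts divided by a size factor of that library. The table held 18088 genes, and no column lacked a sample. Dividing each library by its smallest step gave whole numbers of counts, within a tolerance of 0.01 counts, for 100% of values. For 3 libraries the step was too close to 1 for the deposited values to show this by themselves. The recovered totals ran from 24391022 to 33842466 counts per library, with a median of 27601196.

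Values were analysed as log2(value + 1), which understates the change of low genes, for the 17901 genes with a value of 10 or more in at least 4 libraries. limma 3.58.1 in R 4.3.3 was fitted to all libraries with 1 mean for each of the 12 groups of genotype, drug and sex, leaving 47 residual degrees of freedom, and moderated with a trend on the mean. Comparisons that average the sexes weight both equally. P-values were adjusted by the Benjamini-Hochberg method within each of 20 comparisons fixed before the data were examined, with a threshold of 0.05, and 3 comparisons that average over the other factor were added after the data were examined. As an alternative, the quasi-likelihood test of edgeR 4.0.16 on the recovered counts called 2218 genes between genotypes under vehicle, 95 and 25 with lithium in heterozygous and wild-type mice, and 1210 and 74 with fluoxetine in them.

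The 35 gene lists were fixed before the data were examined and tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation. Genes named by their smallest p in vehicle females, in the comparisons of treated heterozygous with wild-type vehicle mice, between the drugs, and across drugs or genotypes were chosen after their values were seen. The others followed a rule fixed in advance: Dyrk1a in all groups; in each comparison averaged over the sexes the 8 largest rises and 8 largest falls among called genes at or above the median level, without sex-linked and predicted genes; up to 4 members of a list that passed and up to 2 of another list described; up to 8 genes of smallest p in a test of a difference between effects; and Gsk3b, Slc6a4, Htr1a, Htr2a, Htr2c, Rcan1, Fos, Arc and Bdnf where tested. Some genes that the rule names are not reported here. Replicates within groups all differed by more than sampling noise: the chi-square per gene ran from 3.188 to 88.08 over 116 pairs. 20 symbols stood for more than 1 gene identifier and 11 identifiers had no symbol.

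The limma step was tested on simulated counts with 200 changed genes, run on 17901 genes. At a 1.5-fold change it recovered 98% for the genotype comparison under vehicle, 86% for that in females and 82% for lithium by genotype, with 7, 10 and 11 false calls. At a 1.25-fold change it recovered 60%, 40% and 46% in the same order. The list test, simulated for lithium in heterozygous mice, called the 1 shifted list and 0 of 34 others. Genes were drawn independently in these simulations, without the variation that real libraries share between genes. These counts of false calls therefore do not give the error rate in the real libraries. Alternatives fixed in advance were a pseudocount of 5, no filter and a filter of 100, TMM factors, quantile normalization, the replicate number as a block, array weights, striatal and oligodendrocyte list means as covariates, the groups of each comparison alone, edgeR, and leaving out each library. The olfactory bulb covariate, the fit without 2 heterozygous fluoxetine males, and both together were chosen after seeing the data.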

Results

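Gene expression was measured by RNA sequencing in the prefrontal cortex of wild-type mice and of mice heterozygous for a mutation in Dyrk1a, the gene of a kinase whose reduced dosage in people is linked to intellectual disability and autism. Pups had received vehicle, lithium or the serotonin reuptake inhibitor fluoxetine from postnatal day 3 to day 24 through the milk of the treated dam, and tissue was taken at day 25. The 59 libraries fell into 12 groups by genotype, drug and sex, with 5 mice in each group except wild-type fluoxetine males, with 4. The library totals recovered from the deposited values ran from 24391022 to 33842466 counts. Replicate libraries differed by more than counting error, with a chi-square per gene of 3.188 or more in each pair. Levels are given as normalised counts, mean ± SD, and changes as log2 fold changes on the log2(value + 1) scale, with the standard error after ±. The labels do not name litters, and pups of 1 dam share its drug, so p-values measure the spread between these mice and cannot separate litters from treatments.

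The targeted gene was examined first. Dyrk1a (chromosome 16, 94570010 to 94695517 on GRCm38) was not lower in heterozygous mice under vehicle: the level was 2326 ± 65.9 against 2232 ± 55.7 normalised counts in wild-type mice (SD, n = 10 in each), a log2 fold change of 0.06 ± 0.05 (limma adjusted p = 0.451). In females the means were 2355 ± 53.4 and 2217 ± 62.2, and in males 2296 ± 69.0 and 2246 ± 50.9 (SD, n = 5 each). Under lithium, heterozygous mice had 2355 ± 167 in females and 2329.9 ± 129 in males, against 2193 ± 45.0 and 2187 ± 25.4 in wild-type mice (SD, n = 5 each). Under fluoxetine, heterozygous females had 2262 ± 64.5 and wild-type females 2152 ± 54.6 (SD, n = 5 each), and wild-type males had 2171 ± 73.9 (SD, n = 4). Heterozygous fluoxetine males had 2935 ± 812 (SD, n = 5), a spread that came from replicates 3 and 4 with 4214 and 3278. The limma fit pools the spread of all 12 groups, so the standard error of the vehicle comparison includes these replicates. The limma adjusted p of 0.451 therefore does not reflect the spread of the vehicle mice alone. It does not exclude a higher Dyrk1a level in heterozygous vehicle mice. A gene-level sum does not tell the mutant from the normal transcript, so these values neither check nor contradict the genotype labels. Xist and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d matched the labelled sex in all 59 libraries.

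**Figure D1:**
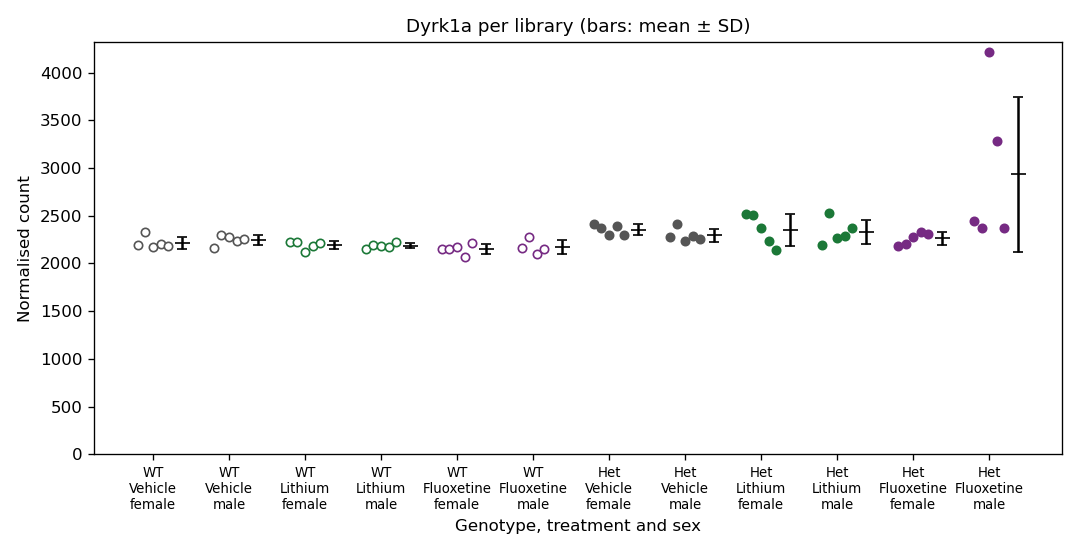
Normalised counts of Dyrk1a in each of the 59 libraries (points; open for wild type, filled for heterozygous) in the 12 groups, with mean ± SD beside the points. Heterozygous fluoxetine male replicates 3 and 4 lie at 4214 and 3278, above the other libraries.

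Libraries differed in markers of a neighbouring tissue. The first principal component held 22.2% of the variance, and its position, with the sign set to be positive, was correlated across the 59 libraries with the mean of the olfactory bulb marker list (Pearson r = 0.96, Spearman rho = 0.99, 2-sided permutation p = 1e-05 for both, the smallest that 100000 permutations can give; r = 0.96 without the 2 libraries farthest from the median). It was the only such relation computed. The list mean, as a log2 deviation from the mean of all libraries, was 1.36 ± 0.96 in heterozygous vehicle males and -1.76 ± 0.76 in wild-type vehicle males (SD, n = 5 each), with no overlap: the lowest heterozygous male lay at -0.11 and the highest wild-type male at -0.45. Vehicle females of both genotypes spread from -2.32 to 1.51. In wild-type fluoxetine mice the list mean was 0.61 ± 0.38 in females (SD, n = 5) and 0.92 ± 0.25 in males (SD, n = 4). The second component, with 10.8% of the variance, set heterozygous fluoxetine male replicates 3 and 4 apart. The glucocorticoid responsive list lay 1.5 and 0.48 above the mean of all libraries in these 2 mice. Each count below was therefore also taken with the olfactory bulb list mean as a covariate, without these 2 libraries, and with both, all 3 chosen after the data were examined.

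**Figure D2:**
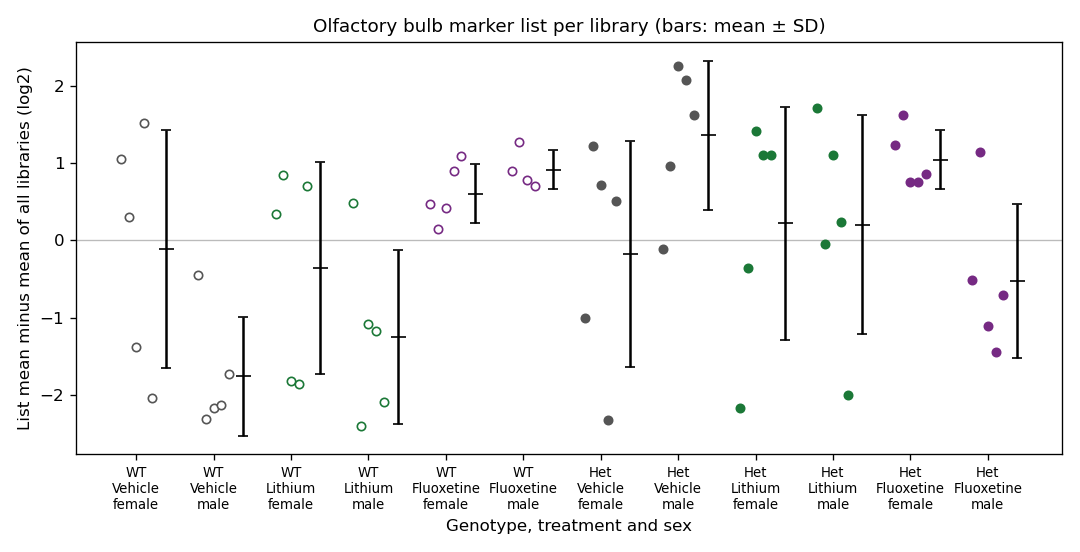
Mean of the 16 olfactory bulb markers in each library, as the log2 deviation from the mean of all 59 libraries (points; open for wild type, filled for heterozygous), with mean ± SD beside the points. Heterozygous vehicle males, from -0.11 to 2.26, all lie above wild-type vehicle males, from -2.31 to -0.45.

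The first comparison asked what the Dyrk1a mutation changed without a drug. Under vehicle, 1079 genes were higher and 1274 lower in heterozygous mice, and olfactory bulb markers led the rise. Doc2g was at 3326 ± 2839 against 1121 ± 1534 (SD, n = 10 in each), a change of 2.06 ± 0.69 (limma adjusted p = 0.0419), higher than the wild-type mean of the same sex in 8 of 10 mice. Cdhr1 (2.04 ± 0.67), Th, the rate-limiting enzyme of dopamine synthesis (1.75 ± 0.60), the calcium-binding protein Calb2 (1.42 ± 0.48), Lgr5 (1.38 ± 0.44), Lgr6 (1.32 ± 0.43), Pbx3 (1.24 ± 0.38) and Cacng5 (1.21 ± 0.35) also rose. The genes that fell most were Lypd6 (-0.62 ± 0.14), Neurod6, a transcription factor of pyramidal neurons (-0.61 ± 0.18), Fam19a1 (-0.60 ± 0.17), Myl4 (-0.58 ± 0.18), Pgm2l1 (-0.57 ± 0.16), Mal2 (-0.57 ± 0.17), the cell adhesion molecule Chl1 (-0.56 ± 0.14) and the interneuron peptide Sst (-0.56 ± 0.13), with adjusted p values of 0.0163 to 0.0377. Of the 16 olfactory bulb markers, 11 rose, 0 fell and 5 did not pass. Their median was 1.68, with 15 higher and 0 lower adjusted over the list alone.

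Several other lists also held called genes between genotypes, in a comparison where the olfactory bulb markers had a median difference of 1.68. Of 34 excitatory postsynapse genes, 1 rose, 12 fell and 21 did not pass (median -0.16; 1 higher and 19 lower adjusted over the list alone). Of 29 presynaptic release genes, 1 rose, 10 fell and 18 did not pass (median -0.16; 1 higher and 15 lower adjusted over the list alone). Of 24 cholesterol biosynthesis genes, 0 rose, 7 fell and 17 did not pass, those that fell including Hmgcs1, the synthase before the rate-limiting step (-0.30 ± 0.08), Msmo1 (-0.32 ± 0.09), Nsdhl (-0.21 ± 0.05) and Sc5d (-0.20 ± 0.05), with 0 higher and 11 lower adjusted over the list alone. Of 30 immediate early genes, which neurons switch on within minutes of activity, 6 rose, 0 fell and 24 did not pass, with Fosb (0.90 ± 0.24), Fosl2 (0.69 ± 0.17), Nr4a2 (0.61 ± 0.19) and Dusp5 (0.62 ± 0.20) higher. In this list 6 were higher and 0 lower adjusted over the list alone. Its mean deviation in heterozygous vehicle mice was 0.42 to 0.69 in replicates 3 to 5 of both sexes and -0.09 to 0.09 in replicates 1 and 2. Of 80 cytosolic ribosomal protein genes, 11 rose, 0 fell and 69 did not pass, with 15 higher and 0 lower adjusted over the list alone. Camera with a preset correlation called 9 of the 35 lists here, 11 with the olfactory bulb covariate, and none with an estimated correlation (each adjusted p = 0.81 with an estimated correlation for the lists just named). Of the genes set for every comparison, Htr1a (-0.28 ± 0.13), Htr2a (-0.26 ± 0.12), Htr2c (-0.50 ± 0.25), Rcan1 (-0.19 ± 0.07), Fos (0.50 ± 0.22), Arc (0.17 ± 0.22), Bdnf (-0.35 ± 0.14) and Gsk3b (-0.08 ± 0.05) did not pass. Slc6a4 was not tested.

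With the olfactory bulb list mean as a covariate no gene was called by limma between genotypes under vehicle, and Lypd6 moved to -0.32. Doc2g moved to -0.08, but it belongs to that list, so the covariate removes its change whatever the cause. With the covariate 1143 genes had an unadjusted p under 0.05, against 5778 without it, where edgeR called 2218. Chance alone gives about 1 in 20 of the 17901 genes tested, and 1143 lies somewhat above that. A fit of only the groups compared called 139. The count fell to 29 without heterozygous vehicle male replicate 3 and rose to 5058 without replicate 1 of that group, and for 16 of the 20 libraries left out in turn it moved by more than 1.5 times.

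Males and females differed in this genotype contrast. In vehicle males 2992 genes were higher and 3580 lower in heterozygous mice, and in vehicle females limma called none, with 631 genes at an unadjusted p under 0.05 and none by edgeR. The female genes with the smallest p, chosen after their values were seen, included Ndn, an imprinted gene of postmitotic neurons, at 3167 ± 966 against 4379.9 ± 555 (SD, n = 5 in each; -0.51 ± 0.10, limma adjusted p = 0.15), lower than the wild-type mean in 4 of 5 mice. The genotype effect itself differed between the sexes at 2857 genes, more positive in females at 1736 and in males at 1121. The smallest p values belonged to Igfn1 (1.89 ± 0.34, female minus male effect), the sialidase Neu2 (1.41 ± 0.27), Fam107a (1.16 ± 0.23), Csrp1 (0.56 ± 0.11), the chaperone clusterin, Clu (0.54 ± 0.11), and Sh2d3c (0.47 ± 0.09), with the predicted genes A730046J19Rik and Gm9916 at low counts. With the olfactory bulb covariate limma called no gene in males or between the sexes, with 982 and 752 genes at an unadjusted p under 0.05. Without heterozygous vehicle male replicate 3, and likewise without replicate 4, the count between the sexes was 0 by limma, with 4337 and 4480 at an unadjusted p under 0.05, and it was 7 without wild-type vehicle female replicate 4. With all libraries edgeR called 6648 genes in males and 2901 between the sexes. A fit of only the groups compared called 4555 in males and 0 between the sexes, where 5804 had an unadjusted p under 0.05. The male count was 4059 without heterozygous vehicle male replicate 3.

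**Figure D3:**
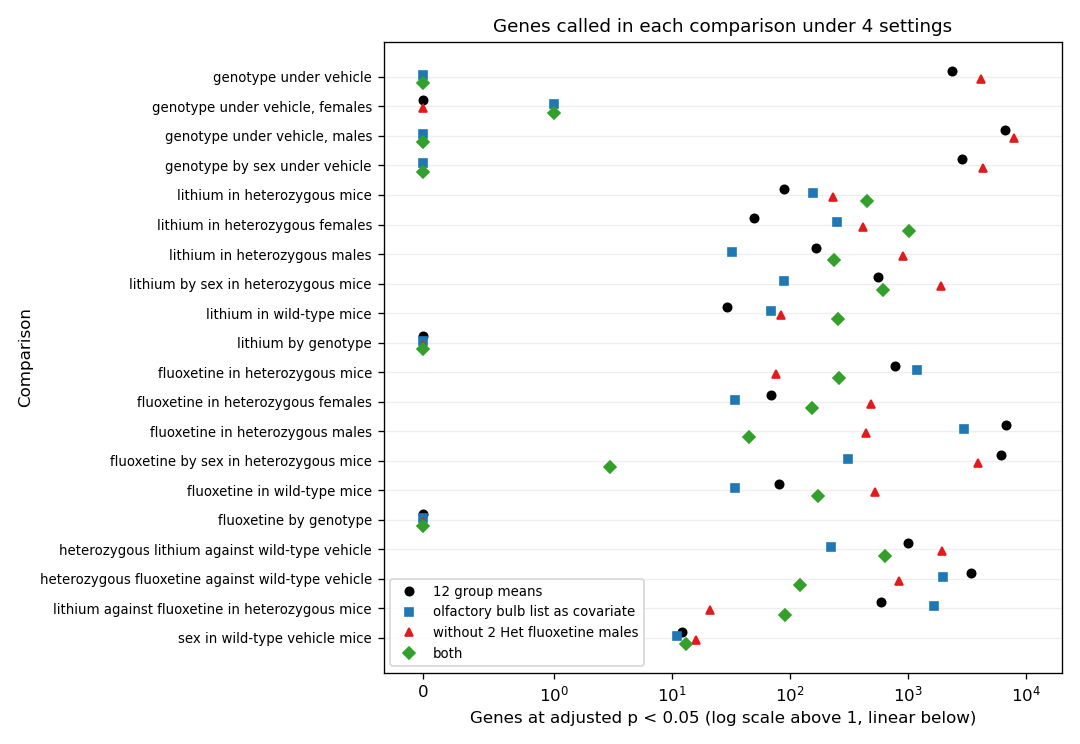
Number of genes at an adjusted p under 0.05 in each of the 20 planned comparisons (log scale above 1) with 12 group means (circles), with the olfactory bulb list as a covariate (squares), without heterozygous fluoxetine male replicates 3 and 4 (triangles) and with both (diamonds). Between genotypes under vehicle the count goes from 2353 to 0 with the covariate, while for lithium in heterozygous mice it goes from 89 to 157.

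Lithium, a direct inhibitor of the kinase GSK3 and of inositol monophosphatase, was compared with vehicle in heterozygous mice. Activity-dependent transcription factors fell: Nr4a2 was at 373 ± 117 against 775 ± 262 (SD, n = 10 in each), a change of -1.06 ± 0.19 (limma adjusted p = 0.00174), below the vehicle mean of the same sex in 10 of 10 mice. Fosb (-1.12 ± 0.24), Fosl2 (-0.95 ± 0.17), Nr4a3 (-0.86 ± 0.16) and Junb (-0.70 ± 0.17) fell too, as did Nab2, a corepressor of EGR factors (-0.47 ± 0.08), Arl4d (-0.48 ± 0.12), the potassium channel Kcnh5 (-0.45 ± 0.11) and Rflnb (-0.26 ± 0.06). Among the genes that rose, Zbtb16, a transcription factor induced by glucocorticoids, went to 1039 ± 98.0 against 677 ± 129.8 (SD, n = 10 in each; 0.64 ± 0.10, limma adjusted p = 0.00034), higher in 10 of 10 mice. The phagocytic receptor Mertk (0.48 ± 0.08), Cemip (0.39 ± 0.09), the thyroid hormone activating enzyme Dio2 (0.39 ± 0.10), Wipf3 (0.37 ± 0.06), Tcea2 (0.37 ± 0.07), Ndn (0.35 ± 0.07) and Banp (0.32 ± 0.07) rose, with adjusted p values of 0.000836 to 0.0465. For Ndn the vehicle mice were uneven: heterozygous vehicle female replicates 3 to 5 were at 2391 to 2559 normalised counts. The other heterozygous vehicle mice were at 3258 to 4603 and the heterozygous lithium mice at 3922 to 5048.

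By list, of 30 immediate early genes 0 rose, 6 fell and 24 did not pass, with a median of -0.41 and 0 higher and 17 lower adjusted over the list alone (camera adjusted p = 1.1e-20; adjusted p = 0.048 with an estimated correlation). The list mean was -0.42 to 0.33 in heterozygous lithium mice. In heterozygous vehicle mice it was 0.42 to 0.69 in replicates 3 to 5 of both sexes and -0.09 to 0.09 in replicates 1 and 2. Fos stood at 404 to 1262 with lithium, against 1299 to 2395 in vehicle replicates 3 to 5 and 660.3 to 816 in 1 and 2. Of 26 unfolded protein and integrated stress response genes 2 rose, 0 fell and 24 did not pass, with 13 higher and 1 lower adjusted over the list alone (adjusted p = 0.13 with an estimated correlation). The endoplasmic reticulum chaperone Hspa5 rose by 0.25 ± 0.06 and the disulfide isomerase Pdia3 by 0.14 ± 0.04, the latter just past the threshold (adjusted p = 0.05 after rounding), while Dnajc3 (0.14 ± 0.04) and Hsp90b1 (0.15 ± 0.04) did not pass. Of 28 myelinating oligodendrocyte genes 0 rose, 2 fell and 26 did not pass, the transcription factor Nkx6-2 (-0.72 ± 0.18) among those that fell, with a median of -0.35 and 0 higher and 22 lower adjusted over the list alone (adjusted p = 0.37 with an estimated correlation). The myelin list mean of heterozygous lithium female replicate 1 was -1.37 relative to all libraries, and the other lithium females lay from -0.28 to 0.10, and without it the median was -0.21. Of 24 cholesterol biosynthesis genes 0 rose, 1 fell and 23 did not pass, the sterol transporter Stard4 (-0.24 ± 0.06), with 0 higher and 3 lower adjusted over the list alone (adjusted p = 0.82 with an estimated correlation). Of 7 blood genes 0 rose, 0 fell and 7 did not pass, with a median of 0.69 and 5 higher and 0 lower adjusted over the list alone (adjusted p = 0.4 with an estimated correlation).

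In all, 44 genes were higher and 45 lower with lithium in heterozygous mice, and all 89 remained called with the same sign with the olfactory bulb covariate, where the count was 157. Of 100 splits of these mice 8 called as many genes, so chance is not excluded for this count. Leaving out 1 library gave 45 (heterozygous vehicle male replicate 4) to 156 genes (heterozygous vehicle male replicate 1), with a move of more than 1.5 times for 9 of 20 libraries. Gsk3b (0.00 ± 0.05), Fos (-0.71 ± 0.22), Arc (-0.66 ± 0.22), Bdnf (0.13 ± 0.14), Rcan1 (0.10 ± 0.07), Htr1a (0.01 ± 0.13), Htr2a (0.13 ± 0.12) and Htr2c (0.20 ± 0.25) did not pass. In females 21 genes were higher and 28 lower, and in males 97 and 67. With only the groups compared limma called 0 in females, with 3071 at an unadjusted p under 0.05, and 1 in males, while edgeR with all libraries called 43 and 200. Chance is not excluded for the male count, which 7 of 100 splits reached. With quantile normalization 59.3% of the female calls were higher, against 42.9% with the deposited scaling. The female count ran from 11 without heterozygous vehicle female replicate 4 to 462 without replicate 2 of that group, and the male count from 2 without heterozygous vehicle male replicate 4 to 3038 without replicate 1. The olfactory bulb list mean was 0.20 ± 1.41 in lithium males and 1.36 ± 0.96 in vehicle males (SD, n = 5 each). The lithium effect differed between the sexes at 549 genes, led by the mitochondrial enzyme Ogdhl (-0.38 ± 0.06, female minus male effect), Sh2d3c (-0.51 ± 0.09), the clock repressor Nr1d1 (-0.47 ± 0.09), Gaa (-0.27 ± 0.05), Hectd3 (-0.31 ± 0.06), Cbfb (0.53 ± 0.11) and Slc43a2 (-0.31 ± 0.06). This count ran from 1 without heterozygous vehicle female replicate 5 to 3127 without heterozygous vehicle male replicate 1, and was 89 with the olfactory bulb covariate and 2 with only the groups compared. Of its calls 25.5% were more positive in females, and 41.8% with quantile normalization.

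In wild-type mice the lithium comparison called 14 genes higher and 15 lower. Zbtb16 rose again, to 1103 ± 179 against 809.5 ± 152 (SD, n = 10 in each; 0.45 ± 0.10, limma adjusted p = 0.0285), and so did Banp (0.32 ± 0.07), Wipf3 (0.28 ± 0.06), Fndc3b (0.27 ± 0.06), Mroh1 (0.25 ± 0.05), the nucleolar protein Rbm28 (0.23 ± 0.04), Rere (0.21 ± 0.05) and Srrm3 (0.21 ± 0.05). The lactate transporter Slc16a1 fell by 0.32 ± 0.06, Pnck by 0.27 ± 0.06, Lrrc75b by 0.26 ± 0.05, the glial transcription factor Sox8 by 0.24 ± 0.05 and the histone methyltransferase Suv39h1 by 0.23 ± 0.05 on the log2 scale. Ctnnb1, the gene of beta-catenin, whose protein GSK3 marks for degradation, dropped by 0.20 ± 0.04, from 19361 ± 1063 to 16855 ± 564 (SD, n = 10 in each; limma adjusted p = 0.0285). Rnf114 (-0.19 ± 0.03) and Tnfaip1 (-0.11 ± 0.02) were lower as well. No member of the immediate early gene list passed over all genes; its median was -0.26, with 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 4.2e-12; adjusted p = 0.24 with an estimated correlation). The values of Arc (-0.73 ± 0.22), Egr2 (-0.68 ± 0.23), Junb (-0.50 ± 0.17) and Nr4a1 (-0.48 ± 0.16) were below 0. For the unfolded protein and integrated stress response list, 13 higher and 0 lower adjusted over the list alone and none over all genes (median 0.11; adjusted p = 0.052 with an estimated correlation), with Creld2 at 0.30 ± 0.08, Sdf2l1 at 0.43 ± 0.13 and Dnajb11 at 0.14 ± 0.04. Of 77 oxidative phosphorylation genes none passed over all genes, with 2 higher and 0 lower adjusted over the list alone (median 0.04; adjusted p = 0.68 with an estimated correlation). Leaving out wild-type vehicle male replicate 3 lowered the count to 13, and 5 of 20 libraries moved it by more than 1.5 times.

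The test of whether lithium acted differently in the 2 genotypes called no gene by limma or edgeR, with 497 genes at an unadjusted p under 0.05. The myelinating oligodendrocyte list had the most negative median among the lists with a camera call in this test, -0.42 (heterozygous minus wild-type effect; adjusted p = 0.49 with an estimated correlation), with none of 28 members past the threshold over all genes, 0 higher and 1 lower adjusted over the list alone and Ppp1r14a at -1.07 ± 0.31 and Nkx6-2 at -0.73 ± 0.26. Heterozygous lithium female replicate 1, at -1.37 in this list, stood below the other lithium females. Without it the median was -0.25 (camera adjusted p = 3.4e-15 with the preset correlation). With that correlation most splits of the same mice called as many lists in this test, so this p is not read as a difference between genotypes.

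With fluoxetine in heterozygous mice, genes that neurons switch on with activity fell. Fos was at 577 ± 169 against 1401 ± 681 (SD, n = 10 in each), a change of -1.17 ± 0.22 (limma adjusted p = 0.00264), below the vehicle mean of the same sex in 10 of 10 mice. The synaptic gene Arc (-1.11 ± 0.22), Nr4a3 (-1.09 ± 0.16), Nr4a1 (-1.03 ± 0.16), Npas4 (-1.0 ± 0.28), Fosl2 (-0.98 ± 0.17), Nr4a2 (-0.97 ± 0.19) and Junb (-0.87 ± 0.17) were the other genes that fell most. Of 30 immediate early genes 0 rose, 15 fell and 15 did not pass, with a median of -0.53 and 0 higher and 19 lower adjusted over the list alone (camera adjusted p = 6.1e-14; adjusted p = 0.26 with an estimated correlation). The list mean was -0.48 to 0.39 in heterozygous fluoxetine mice. The heterozygous vehicle mice were again uneven. Fos was 1299 to 2395 in vehicle replicates 3 to 5 of both sexes, 660.3 to 816 in replicates 1 and 2, and 327 to 906 with fluoxetine. Arc was 5034 to 6071, 2025 to 3119 and 1306 to 3049 in the same order. Fkbp5, a glucocorticoid-induced cochaperone of the glucocorticoid receptor, was at 2145 ± 2369 against 882 ± 67.0 (SD, n = 10 in each; 0.85 ± 0.17, limma adjusted p = 0.00512). The opioid precursor Pdyn (0.67 ± 0.17), the astrocyte filament Gfap (0.63 ± 0.18), Gpr22 (0.61 ± 0.15), Igfbp3 (0.59 ± 0.11), Cgref1 (0.55 ± 0.16), Bok (0.53 ± 0.14) and Zbtb16 (0.49 ± 0.10) rose. Of 22 glucocorticoid responsive genes 5 rose, 1 fell and 16 did not pass, with Hif3a (0.69 ± 0.12) and Map3k6 (0.84 ± 0.18) higher, and 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.92 with an estimated correlation). Of 23 interferon response genes 5 rose, 0 fell and 18 did not pass, those that rose including Rsad2 (0.81 ± 0.18), Irf7 (0.84 ± 0.22), Xaf1 (0.43 ± 0.12) and Rtp4 (0.43 ± 0.13), with 8 higher and 0 lower adjusted over the list alone (adjusted p = 0.92 with an estimated correlation). Of 24 cholesterol biosynthesis genes 0 rose, 6 fell and 18 did not pass, with 0 higher and 10 lower adjusted over the list alone. Of these Stard4 (-0.31 ± 0.06), Srebf2 (-0.14 ± 0.03), Mvk (-0.24 ± 0.06) and Cyp51 (-0.22 ± 0.06) had the smallest p (adjusted p = 0.92 with an estimated correlation). Of 28 myelinating oligodendrocyte genes 0 rose, 1 fell and 27 did not pass, Gal3st1 (-0.31 ± 0.09), with 0 higher and 1 lower adjusted over the list alone (adjusted p = 0.94 with an estimated correlation).

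Male replicates 3 and 4 of this group stood apart in some of these genes. Their Fkbp5 levels were 8496 and 3668 against 1075, 1297 and 1153 in replicates 1, 2 and 5, and their Gfap levels 14903 and 14114 against 5664, 4614 and 3183. The 764 genes called with all libraries (396 higher, 368 lower) became 76 without both, of which 63 were among the first set. A fit of only the groups compared called 2, and 7 of 100 splits of these mice called as many genes as the real groups, so chance is not excluded for this count. Fkbp5, Fos, Arc, Nr4a1, Nr4a3, Fosl2, Nr4a2, Junb, Igfbp3, Zbtb16, Hif3a, Map3k6, Stard4 and Srebf2 stayed past the threshold without them, with Fkbp5 at 0.40. Those that did not, with their log2 fold change without the 2 males, were Pdyn (0.38), Gfap (0.28), Gpr22 (0.35), Cgref1 (0.18), Bok (0.18), Npas4 (-0.65), Mvk (-0.13), Gal3st1 (-0.18), Rsad2 (0.58), Irf7 (0.60), Xaf1 (0.28), Rtp4 (0.43) and Cyp51 (-0.20), at adjusted p values of 0.134 to 0.578. Rtp4 and Cyp51 hardly moved in size. Dyrk1a (0.13 ± 0.05), Gsk3b (-0.01 ± 0.05), Htr1a (-0.10 ± 0.13), Htr2a (0.31 ± 0.12), Htr2c (0.49 ± 0.25), Bdnf (0.30 ± 0.14) and Rcan1 (0.11 ± 0.07) did not pass with all libraries. In females 19 genes were higher and 49 lower, and in males 3677 and 3049. With only the groups compared limma called 229 in females and 0 in males, where 4136 had an unadjusted p under 0.05 and edgeR with all libraries called 6833. The fluoxetine effect differed between the sexes at 6136 genes, led by Agmat (-4.78 ± 0.69, female minus male effect), Git1 (-0.66 ± 0.10), the dopamine signalling protein Ppp1r1b (-2.35 ± 0.37), Anxa11 (-1.35 ± 0.22), Pih1d1 (-0.96 ± 0.16), Kif17 (-1.20 ± 0.20), Nr1d1 (-0.55 ± 0.09) and Plcxd1 (-1.37 ± 0.23). The count between the sexes was 3852 without the 2 males, 310 with the olfactory bulb covariate, 3 with both and 2723 with only the groups compared. The male count was 437 without the 2 males, 2940 with the covariate and 45 with both. Ppp1r1b was at 8896 and 7867 in male replicates 3 and 4, against 1235 to 2339 in the other males of the group. The female count ran from 7 without heterozygous fluoxetine female replicate 2 to 677 without heterozygous vehicle female replicate 2. Of the female calls 27.9% were higher with the deposited scaling, 42% with TMM factors and 40.3% with quantile normalization.

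In wild-type mice, genes of sterol synthesis fell with fluoxetine. Stard4 was at 766 ± 58.8 against 1063 ± 111 (SD, n = 9 and 10), a change of -0.47 ± 0.06 (limma adjusted p = 8.41e-06), below the vehicle mean of the same sex in 9 of 9 mice. Of 24 cholesterol biosynthesis genes 0 rose, 7 fell and 17 did not pass, with 0 higher and 20 lower adjusted over the list alone (median -0.25; camera adjusted p = 1.8e-21; adjusted p = 0.03 with an estimated correlation): Cyp51 (-0.35 ± 0.06), Idi1 (-0.33 ± 0.07) and the epoxidase Sqle (-0.28 ± 0.06) were among those that fell. Arc (-1.05 ± 0.23), Junb (-0.72 ± 0.17), Nr4a3 (-0.67 ± 0.16), Klf10 (-0.64 ± 0.13), the phosphatase Dusp6 (-0.44 ± 0.11) and Nr3c1, the glucocorticoid receptor (-0.42 ± 0.09), fell as well. Of 30 immediate early genes 0 rose, 4 fell and 26 did not pass, with a median of -0.26 and 0 higher and 12 lower adjusted over the list alone (adjusted p = 0.34 with an estimated correlation). The genes that rose most were Igsf3 (0.63 ± 0.16), Cpne6 (0.62 ± 0.15), Hs3st1 (0.42 ± 0.10), the processed pseudogene Rpl28-ps1 (0.35 ± 0.09), whose reads cannot be told from those of its parent gene with certainty, the reelin receptor Lrp8 (0.24 ± 0.06), Igsf11 (0.23 ± 0.06), Rere (0.23 ± 0.05) and Ccsap (0.22 ± 0.04). Hif3a (0.64 ± 0.12) rose and Pdk4 (-0.43 ± 0.09) fell, both in the glucocorticoid responsive list. The olfactory bulb list was higher with fluoxetine in these mice, with a median of 1.84, no member past the threshold over all genes and 16 higher and 0 lower adjusted over the list alone (adjusted p = 0.34 with an estimated correlation). No interferon response gene passed (median 0.19; 0 higher and 0 lower adjusted over the list alone; adjusted p = 0.71 with an estimated correlation).

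In all 33 genes were higher and 47 lower, and 14 of these kept their call with the olfactory bulb covariate, Stard4 and Arc among them. Leaving out wild-type fluoxetine male replicate 4 left 13 genes and leaving out wild-type vehicle female replicate 4 gave 376, while a fit of only the groups compared called 1151. The test of a different fluoxetine effect between genotypes called no gene by limma or edgeR, with 3917 genes at an unadjusted p under 0.05, but limma called 1277 without heterozygous fluoxetine male replicate 2, 64 without replicate 5 of that group, 1226 without heterozygous vehicle male replicate 1 and 3173 with array weights. The olfactory bulb list had a median of -2.28 in that test (adjusted p = 0.98 with an estimated correlation).

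**Figure D4:**
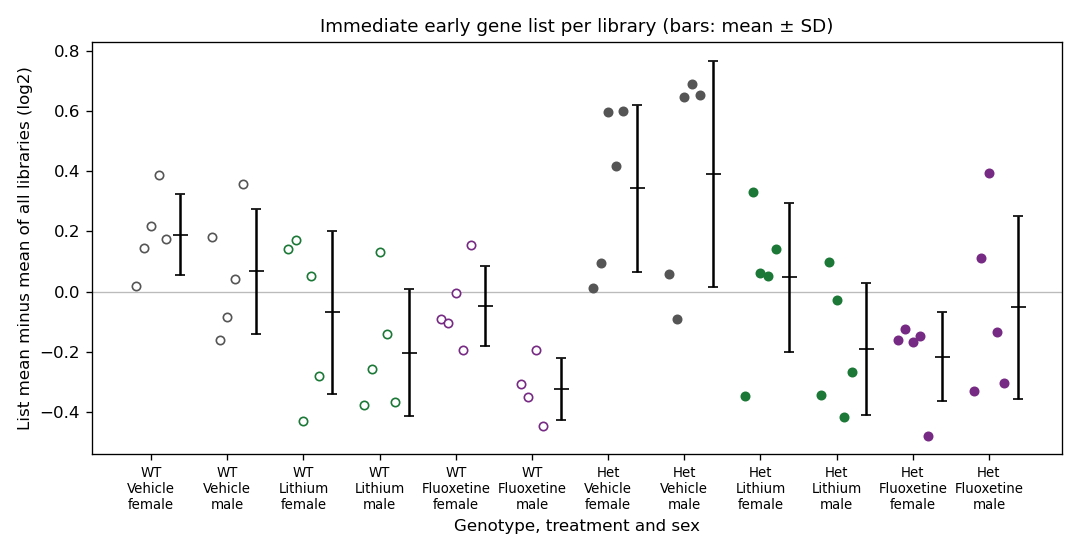
Mean of the 30 immediate early genes in each library, as the log2 deviation from the mean of all 59 libraries (points; open for wild type, filled for heterozygous), with mean ± SD beside the points. The group means are 0.34 and 0.39 in heterozygous vehicle females and males, where replicates 3 to 5 lie at 0.42 to 0.69 and replicates 1 and 2 at -0.09 to 0.09, and -0.22 and -0.05 in heterozygous fluoxetine females and males.

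Treated heterozygous mice were also set against untreated wild-type mice, to see what separated them after treatment. With lithium 518 genes were higher and 484 lower than in wild-type vehicle mice, and with fluoxetine 1646 and 1764. The smallest p values, chosen after the values were seen, were for lithium those of Dnajc27 (-0.20 ± 0.02), the zinc transporter Slc30a9 (-0.18 ± 0.02), Stard4 (-0.42 ± 0.06), Rbm28 (0.27 ± 0.04) and Pnrc1 (0.28 ± 0.04). For fluoxetine they were those of Stard4 (-0.49 ± 0.06), the mitochondrial carrier Ucp2 (0.70 ± 0.09), Fam214a (0.52 ± 0.08), Cyp51 (-0.40 ± 0.06) and the prohormone convertase Pcsk1 (-0.47 ± 0.07). With the olfactory bulb covariate the counts were 222 and 1980, and without the 2 males the fluoxetine count was 831. Lithium and fluoxetine were compared directly in heterozygous mice at 588 called genes, 304 higher and 284 lower with lithium. Ctnnb1 had the smallest p, also chosen after the values were seen, at 16409 ± 470.4 against 20383 ± 3392 (SD, n = 10 in each; -0.30 ± 0.04, limma adjusted p = 0.000185), followed by Cuta (0.20 ± 0.04), Rbm28 (0.22 ± 0.04), the nucleolar protein nucleolin, Ncl (-0.21 ± 0.04), and Ints1 (0.18 ± 0.03). Without heterozygous fluoxetine male replicates 3 and 4 Ctnnb1 differed by -0.20 (adjusted p = 0.000615). Without these 2 males the count between the drugs was 21. With only the groups compared limma called 0, with 2042 at an unadjusted p under 0.05, and edgeR with all libraries called 1126. With only the groups compared the counts against wild-type vehicle were 675 for lithium and 1068 for fluoxetine. Without heterozygous lithium male replicate 1 the lithium count against wild-type vehicle was 340.

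Whether a drug moved the transcriptome of heterozygous mice back was measured as the correlation, across 17901 genes, of the genotype effect under vehicle with the drug effect; genes are not independent replicates. The correlation was -0.5 for lithium and -0.39 for fluoxetine. Both comparisons use the heterozygous vehicle libraries, and unchanged groups simulated with the same sharing gave a mean of -0.47 for lithium (range -0.84 to -0.1 over 100 draws). For fluoxetine they gave -0.47 (range -0.8 to 0.32), so neither lay outside what shared libraries give with no effect. The covariance was -0.02458 for lithium against a simulated -0.01245, and -0.0242 for fluoxetine against -0.01248. With the heterozygous vehicle libraries split between the 2 effects, the mean correlation over 100 splits was -0.17 for lithium (range -0.43 to 0.39) and -0.14 for fluoxetine (range -0.4 to 0.34). Of the genes higher in heterozygous mice, 7 were called lower with lithium, where independent lists give 2.71, and of those lower 12 were called higher, where independent lists give 3.13. For fluoxetine the overlaps were 47 against 22.2 and 50 against 28.2. The effects of lithium and fluoxetine in heterozygous mice correlated at 0.46 (simulated mean 0.45, range -0.01 to 0.76), with a covariance of 0.01881 against a simulated 0.01188, and at a mean of 0.09 with split vehicle libraries. They shared 15 genes higher with both drugs, where independent lists give 0.973, and 21 genes lower with both, where independent lists give 0.925. Simulated unchanged groups shared 0 genes in each direction in every draw. With split vehicle libraries, and so fewer libraries in each effect, the overlaps in the order just given were 0 to 1 and 0 to 2 for lithium. They were 0 to 3 and 0 to 2 for fluoxetine, and 0 to 7 and 0 to 5 for both drugs. The simulation leaves out real effects and independent lists leave out the shared libraries, so the excess over either is not read as a shared effect.

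Sex was tested in wild-type vehicle mice as a check of the labels. Of the 12 genes called, Xist, Eif2s3x, Kdm5c, Kdm6a and Rab10os were higher in females and Uty, Kdm5d, Eif2s3y, Ddx3y, Uba1y, Gm29650 and Lair1 higher in males. The X-linked Eif2s3x (chromosome X, 94188707 to 94212862), which escapes X inactivation, was at 4722 ± 226 against 3174 ± 124 (SD, n = 5 in each), a change of 0.57 ± 0.06 (limma adjusted p = 1.53e-09), and Kdm5c and Kdm6a differed by 0.35 ± 0.06 and 0.34 ± 0.06. Outside the sex chromosomes, the inhibitory receptor Lair1 (chromosome 7, 4003402 to 4063204) differed by -0.33 ± 0.07 and the antisense transcript Rab10os by 0.42 ± 0.09.

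A comparison added after the data were examined, with its genes chosen after their values were seen, averaged the genotype effect over vehicle, lithium and fluoxetine, 30 heterozygous against 29 wild-type mice. Dyrk1a itself was higher in heterozygous mice, 2422 ± 393 against 2195 ± 57.4 (SD, n = 30 and 29), a change of 0.13 ± 0.03 (limma adjusted p = 0.00768). Its paralog Dyrk1b (chromosome 7, 28179469 to 28187294) rose by 0.11 ± 0.02, from 644 ± 28.7 to 697 ± 41.1, and Dcaf7 (chromosome 11, 106036872 to 106059324), which encodes a scaffold that binds the DYRK1A protein, rose by 0.11 ± 0.02, higher than the matched wild-type mean in 29 of 30 mice. The smallest p belonged to Pnrc1, a nuclear receptor coactivator, at 828 ± 79.7 against 709.7 ± 40.8 (0.22 ± 0.02, limma adjusted p = 4.86e-08), higher in 30 of 30 mice. Rfx5 (0.25 ± 0.03), Ucp2 (0.41 ± 0.05), Fam214a (0.32 ± 0.05), Mxd4 (0.15 ± 0.02), the complement component C4b (0.55 ± 0.10), Trp53inp1 (0.31 ± 0.06) and 2 genes of PI3K regulation, Pik3r3 (0.22 ± 0.03) and Pik3ip1 (0.26 ± 0.04), rose. The potassium channel Kcnc2 (-0.21 ± 0.04), the calcineurin regulator Rcan2 (-0.16 ± 0.03), Dpy19l3 (-0.18 ± 0.03) and Dnajc27 (-0.07 ± 0.01) fell. All of these stayed past the threshold with the olfactory bulb covariate and without the 2 heterozygous fluoxetine males, where Dyrk1a was at 0.10 (adjusted p = 4.45e-05). The total of 3823 genes, however, fell to 80 with the covariate and to 48 with both.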

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

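The tests on striatal and white matter tissue, on the 2 heterozygous fluoxetine males and on the immediate early genes were chosen after the results were seen, as were the 3 comparisons that average over genotypes or drugs; the tests on olfactory bulb tissue, on the Dyrk1a genotype and the splits of the planned comparisons were set before theirs. Of 216 sets of replicates examined, 11 held a library far from the others, where chance gives about 1 in 20, or 10.8. These were Dyrk1a in heterozygous vehicle male replicate 2 (2415.1 against 2240 to 2288 normalised counts in the others) and wild-type vehicle female replicate 2 (2327 against 2176 to 2203), Htr1a in heterozygous vehicle female replicate 2 (466.6 against 576.9 to 605.9) and Fos in heterozygous fluoxetine female replicate 5 (326.6 against 590.9 to 668.4). Among mean log2 levels of lists, the immediate early genes stood at 8.79 against 9.101 to 9.146 in the same female, the glucocorticoid responsive list at 9.49 against 9.165 to 9.174 in wild-type fluoxetine male replicate 4, and the unfolded protein list at 10.07 against 9.985 to 9.997 in wild-type fluoxetine male replicate 3. The myelinating oligodendrocyte list stood at 8.62 against 9.71 to 10.09 in heterozygous lithium female replicate 1 and at 10.2 against 10.09 to 10.12 in wild-type lithium female replicate 2. The interferon response list stood at 6.56 against 6.827 to 6.92 in wild-type vehicle female replicate 2, and the striatal list at 8.05 against 7.157 to 7.4 in heterozygous fluoxetine male replicate 5. Females and males differed, by the test of the difference itself, at 2857 genes for genotype, 549 for lithium and 6136 for fluoxetine in heterozygous mice. With the olfactory bulb covariate limma called 0, 89 and 310. Leaving out 1 library gave lowest limma counts of 0, 1 and 4690.

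The first pattern is the set of genotype calls under vehicle, none of which passed in limma with the olfactory bulb covariate and without the 2 males. Lypd6 went from -0.62 ± 0.14 to -0.30 ± 0.11. Doc2g went from 2.06 ± 0.69 to -0.04 ± 0.08, but it belongs to the olfactory bulb list, so the covariate removes its change whatever the cause. Over 2342 of the called genes outside the olfactory bulb list, the genotype change correlated at 0.92 across genes, which are not independent replicates, with the slope on that list within the drug groups of 39 other libraries, and 2310 had the sign the slope predicts, while over all tested genes the correlation was 0.72, so olfactory bulb tissue in the dissected samples is a candidate explanation. With both sexes averaged, striatal and white matter list means as covariates gave 39 calls, against 2353 without them, so that tissue also stays a candidate for these calls. In males they gave 6294, against 6572 without them, which argues against that tissue as the source of the male calls. The genotype itself stays open: with the olfactory bulb covariate 82.8% of the called genes had the same sign between genotypes in lithium mice, where the highest 5% of permuted labels began at 82.9%, and 84.5% in fluoxetine mice, where it began at 75.7%. In vehicle males the genotype and the tissue content cannot be told apart for these genes, since the genotypes did not overlap in the olfactory bulb list. Vehicle females did overlap in it, at -2.32 to 1.21 in heterozygous and -2.03 to 1.51 in wild-type mice, and there limma called 0 genes. With fewer mice in that comparison a small genotype effect could be missed, so the female count does not decide between the 2.

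The second pattern is the distance of heterozygous fluoxetine male replicates 3 and 4 from the rest. Ppp1r1b was 2.64 (log2) higher in them than in the other 57 libraries, while the median over 13 other abundant striatal markers was 0.18 (SD over markers 1.11): 8 were higher, Rgs9, Pdyn and Penk most (2.32, 1.71 and 1.08), while Rarb and Rxrg stood at -1.13 and -1.49, and striatal tissue would raise them all, which argues against it as the whole source. The lower of their totals was 27725425 counts, inside the range of the other libraries, which argues against low depth. The lower of their glucocorticoid responsive list means was 0.24 above the highest of all other libraries, and of the 35 lists 1 had both mice above and 2, microglia and inhibitory synapse, both below all others. A glucocorticoid response in these 2 mice may therefore account for part of the pattern, as a hypothesis found and tested on the same values. Inhba (3521 and 2770), Gadd45b (3073 and 565) and Cdkn1a (11387 and 2289) were also above all other libraries, whose highest values were 744, 430 and 1908. Whether such a response raised these genes was not tested. Fluoxetine itself stays open, although the other males of the group received it too.

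The third pattern is the lower level of immediate early genes with both drugs. In wild-type mice, whose fold changes use no heterozygous library, the list median was -0.26 with lithium and -0.26 with fluoxetine. Both medians, and those against wild-type vehicle mice below, rest on the same wild-type vehicle libraries and so are not independent. The list means of those libraries lay from -0.16 to 0.39, and a high level in them stays open as a source too. In heterozygous mice high vehicle libraries stay open as a source: replicates 3 to 5 of the vehicle group were higher than 1 and 2 in both sexes, and against wild-type vehicle mice the median was -0.21 with lithium and -0.23 with fluoxetine, the list mean differing by -0.2 ± 0.1 and -0.26 ± 0.1 (SE), in comparisons that differ in genotype as well. With the olfactory bulb covariate the median in heterozygous lithium mice was -0.33, against -0.41 without it, which argues against that tissue as the whole source. Litter, or the day and handling before sampling, could lower such genes and cannot be told apart from the drugs, since the labels give a litter or date for 0 libraries, and an effect of the drugs stays open as well.

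For each comparison the count of called genes was set against 100 splits of the same mice, the real one included. The number of splits with as many genes, with the real count and the highest other in parentheses, was 3 for genotype under vehicle (2353, highest other 5418), 2 for genotype in males (6572, highest other 7046) and 4 for genotype by sex (2857, highest other 5127). It was 2 for lithium in heterozygous females (49, highest other 106), 4 for lithium by sex (549, highest other 5225) and 1 for lithium in wild-type mice (29, highest other 1). It was 2 for fluoxetine in heterozygous females (68, highest other 821), 2 for fluoxetine in heterozygous males (6726, highest other 7957) and 1 for fluoxetine by sex (6136, highest other 5555). It was 1 for fluoxetine in wild-type mice (80, highest other 1), 1 for heterozygous lithium against wild-type vehicle (1002, highest other 40) and 1 for heterozygous fluoxetine against wild-type vehicle (3410, highest other 72). It was 2 for lithium against fluoxetine (588, highest other 2223), 1 for sex (12, highest other 7) and 1 for genotype across drugs (3823, highest other 1397). It was 3 for lithium across genotypes (380, highest other 3631) and 3 for fluoxetine across genotypes (553, highest other 3353). For all of these the share of splits was under 0.05, with no allowance for the number of comparisons. The splits shuffle single mice, so they cannot exclude chance differences between litters or days, which the labels do not give. For the differences between the sexes they shuffle genotype or drug within each sex, so they do not test a sex difference by itself. Chance is not excluded for 3 others, where the number was 8 for lithium in heterozygous mice (89, highest other 4633), 7 for lithium in heterozygous males (164, highest other 6401) and 7 for fluoxetine in heterozygous mice (764, highest other 5523). Every split reaches a count of 0, so the splits do not decide where limma called none: the number was 100 for genotype in females (0, highest other 15), 100 for lithium by genotype (0, highest other 4755) and 100 for fluoxetine by genotype (0, highest other 1252). Splits that called at least 3 times the real count, of which there were 7 for lithium in heterozygous mice, 6 for lithium in heterozygous males, 3 for lithium by sex, 4 for fluoxetine in heterozygous mice, 1 for fluoxetine in heterozygous females, 1 for lithium against fluoxetine, 1 for lithium across genotypes and 1 for fluoxetine across genotypes, point to a structure of the samples other than the groups. The number of splits that called as many lists with a preset correlation was 68 for genotype under vehicle (9 lists, highest other 18), 74 for lithium in heterozygous mice (8 lists, highest other 16), 82 for lithium in wild-type mice (8 lists, highest other 18), 88 for fluoxetine in heterozygous mice (5 lists, highest other 15), 77 for fluoxetine in wild-type mice (10 lists, highest other 19), 65 for lithium by genotype (9 lists, highest other 18) and 72 for fluoxetine by genotype (8 lists, highest other 16), so chance is not excluded for these counts of lists. For the mean moderated t of the immediate early genes it was 1 for lithium in heterozygous mice (-2.58, farthest other 2.41), 2 for lithium in wild-type mice (-1.61, farthest other 1.70), 1 for fluoxetine in heterozygous mice (-2.86, farthest other -2.54) and 1 for fluoxetine in wild-type mice (-1.88, farthest other 1.72). The share was under 0.05 for all 4, with the same limit for litters and days.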

How the results depend on the processing

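The tests with the olfactory bulb covariate, without the 2 heterozygous fluoxetine males and with both, and the 3 comparisons across drugs or genotypes, were chosen after the results were seen. A pseudocount of 5, no filter and TMM factors kept every count within 1.5 times. For the values that moved, the cause was not tested. A filter of 100 gave 315 for lithium in heterozygous males, 920 for lithium by sex and 134 for fluoxetine in heterozygous females. Quantile normalization gave 1 for genotype in females, 81 for lithium in heterozygous females and 444 for lithium in heterozygous males. edgeR gave 1210 for fluoxetine in heterozygous mice and 1126 for lithium against fluoxetine. Array weights gave 7567 for genotype under vehicle, 3 for genotype in females, 10090 for genotype in males, 6858 for genotype by sex, 1052 for lithium in heterozygous mice and 3766 for lithium in heterozygous females. This setting gave 5014 for lithium in heterozygous males, 6664 for lithium by sex, 209 for lithium in wild-type mice, 3885 for fluoxetine in heterozygous females, 3110 for fluoxetine in wild-type mice and 3173 for fluoxetine by genotype. This setting gave 5425 for heterozygous lithium against wild-type vehicle, 51 for lithium against fluoxetine, 7427 for genotype across drugs, 1561 for lithium across genotypes and 1057 for fluoxetine across genotypes. Fitting only the groups of the comparison, with fewer samples, gave 139 for genotype under vehicle, 0 for genotype by sex, 0 for lithium in heterozygous females, 1 for lithium in heterozygous males, 2 for lithium by sex and 57 for lithium in wild-type mice. This setting gave 2 for fluoxetine in heterozygous mice, 229 for fluoxetine in heterozygous females, 0 for fluoxetine in heterozygous males, 2723 for fluoxetine by sex, 1151 for fluoxetine in wild-type mice and 1068 for heterozygous fluoxetine against wild-type vehicle. This setting gave 0 for lithium against fluoxetine, 656 for lithium across genotypes and 250 for fluoxetine across genotypes. Striatal and oligodendrocyte covariates gave 39 for genotype under vehicle, 44 for lithium in heterozygous mice, 66 for lithium in heterozygous males, 1281 for lithium by sex, 75 for fluoxetine in heterozygous mice and 123 for fluoxetine in heterozygous females. This setting gave 2575 for fluoxetine in heterozygous males, 1908 for heterozygous fluoxetine against wild-type vehicle and 230 for fluoxetine across genotypes. The olfactory bulb covariate gave 0 for genotype under vehicle, 1 for genotype in females, 0 for genotype in males, 0 for genotype by sex, 157 for lithium in heterozygous mice and 248 for lithium in heterozygous females. This setting gave 32 for lithium in heterozygous males, 89 for lithium by sex, 69 for lithium in wild-type mice, 1193 for fluoxetine in heterozygous mice, 34 for fluoxetine in heterozygous females and 2940 for fluoxetine in heterozygous males. This setting gave 310 for fluoxetine by sex, 34 for fluoxetine in wild-type mice, 222 for heterozygous lithium against wild-type vehicle, 1980 for heterozygous fluoxetine against wild-type vehicle, 1640 for lithium against fluoxetine and 80 for genotype across drugs. This setting gave 673 for lithium across genotypes and 1518 for fluoxetine across genotypes. Fits without heterozygous fluoxetine male replicates 3 and 4 gave 4083 for genotype under vehicle, 230 for lithium in heterozygous mice, 414 for lithium in heterozygous females, 907 for lithium in heterozygous males, 1878 for lithium by sex and 84 for lithium in wild-type mice. This setting gave 76 for fluoxetine in heterozygous mice, 484 for fluoxetine in heterozygous females, 437 for fluoxetine in heterozygous males, 3852 for fluoxetine by sex, 522 for fluoxetine in wild-type mice and 1934 for heterozygous lithium against wild-type vehicle. This setting gave 831 for heterozygous fluoxetine against wild-type vehicle, 21 for lithium against fluoxetine and 809 for lithium across genotypes. Both together gave 0 for genotype under vehicle, 1 for genotype in females, 0 for genotype in males, 0 for genotype by sex, 447 for lithium in heterozygous mice and 1007 for lithium in heterozygous females. This setting gave 254 for lithium in wild-type mice, 256 for fluoxetine in heterozygous mice, 152 for fluoxetine in heterozygous females, 45 for fluoxetine in heterozygous males, 3 for fluoxetine by sex and 170 for fluoxetine in wild-type mice. This setting gave 637 for heterozygous lithium against wild-type vehicle, 121 for heterozygous fluoxetine against wild-type vehicle, 91 for lithium against fluoxetine, 48 for genotype across drugs, 1460 for lithium across genotypes and 968 for fluoxetine across genotypes. The counts of 0 are limma's, and at an unadjusted p under 0.05 the number was, with only the groups compared, 5804 for genotype by sex, 3071 for lithium in heterozygous females, 4136 for fluoxetine in heterozygous males and 2042 for lithium against fluoxetine. Likewise it was, with the olfactory bulb covariate, 1143 for genotype under vehicle, 982 for genotype in males and 752 for genotype by sex, and, with both, 1595 for genotype under vehicle, 1308 for genotype in males and 1205 for genotype by sex. With all libraries edgeR called 2901 for genotype by sex, 43 for lithium in heterozygous females, 6833 for fluoxetine in heterozygous males, 1126 for lithium against fluoxetine, 2218 for genotype under vehicle and 6648 for genotype in males. Of the lists, 2 were called over the 7 planned comparisons with an estimated correlation, against 57 with the preset one. Across genotypes, lithium and fluoxetine had 2 and 2 more with an estimated correlation. Over the planned comparisons leaving out 1 library gave 50 to 66. Genes too shallow for a value of 10 in 4 libraries were not tested at this depth.

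Between genotypes under vehicle the log2 fold change changed sign with the olfactory bulb covariate for Calb2 at -0.07, Cdhr1 at -0.02, Doc2g at -0.08 and Th at -0.11, and with both for Calb2 at -0.06, Doc2g at -0.04 and Th at -0.11. Cdhr1 and Doc2g belong to the olfactory bulb list itself, so the covariate removes their change whatever the cause. Over the named genes and all alternatives, 6643 values kept their direction and side of the threshold, 941 kept the direction and lost the call, 59 gained it and 7 changed sign with a call in either fit. Another 38 changed sign without a call in either. Among genes called in either comparison the correlation was -0.78 for the genotype and lithium effects and 0.73 for the lithium and fluoxetine effects. Picking as many genes of smallest p in simulated unchanged groups gave means (and ranges) of -0.68 (-0.95 to -0.30) for the genotype and lithium effects and 0.68 (0.17 to 0.94) for the lithium and fluoxetine effects. The correlations therefore lie inside what shared libraries and the choice of genes give with no effect. With split vehicle libraries the correlation was -0.17 for the genotype and lithium effects, -0.14 for the genotype and fluoxetine effects and 0.09 for the lithium and fluoxetine effects.

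Over all groups the replicate numbers did not pair the mice, which does not exclude a shared split in some of them. In heterozygous vehicle mice of both sexes the immediate early gene list mean was 0.42 to 0.69 in replicates 3 to 5. It was -0.09 to 0.09 in replicates 1 and 2. Libraries with the same number in different groups had a mean correlation of deviations of -0.007, against 0.002 for different numbers. In 0 of 66 pairs of groups was every such correlation over 0.1, and 8 of 59 libraries correlated best with their own number. With the number as a block the count was 74 for lithium in heterozygous females, 70 for lithium in heterozygous males and 355 for lithium by sex, and it moved no other count by more than 1.5 times (genotype under vehicle, 1930).

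Leaving out 1 library at a time gave counts of 29 to 5058 for genotype under vehicle, 0 to 1 for genotype in females, 4059 to 7873 for genotype in males, 0 to 4961 for genotype by sex, 45 to 156 for lithium in heterozygous mice and 11 to 462 for lithium in heterozygous females. It gave 2 to 3038 for lithium in heterozygous males, 1 to 3127 for lithium by sex, 13 to 33 for lithium in wild-type mice, 0 to 1 for lithium by genotype, 239 to 2475 for fluoxetine in heterozygous mice and 7 to 677 for fluoxetine in heterozygous females. It gave 4175 to 7766 for fluoxetine in heterozygous males, 4690 to 7247 for fluoxetine by sex, 13 to 376 for fluoxetine in wild-type mice, 0 to 1277 for fluoxetine by genotype, 340 to 1853 for heterozygous lithium against wild-type vehicle and 2009 to 4747 for heterozygous fluoxetine against wild-type vehicle. It gave 64 to 2483 for lithium against fluoxetine, 9 to 14 for sex, 2547 to 5202 for genotype across drugs, 290 to 481 for lithium across genotypes and 358 to 1316 for fluoxetine across genotypes. Where limma called 0 genes, the number at an unadjusted p under 0.05 was 396 to 816 for genotype in females, 4337 to 4480 for genotype by sex, 356 to 716 for lithium by genotype and 3121 to 4514 for fluoxetine by genotype. Single libraries moved some counts by more than 1.5 times. For genotype in females, 0 calls became 1 without heterozygous vehicle female replicate 1 and 1 without heterozygous vehicle female replicate 2. For genotype in males, 6572 calls became 4059 without heterozygous vehicle male replicate 3. For lithium in wild-type mice, 29 calls became 18 without wild-type lithium female replicate 2, 18 without wild-type lithium female replicate 3, 16 without wild-type lithium male replicate 2, 16 without wild-type vehicle female replicate 2 and 13 without wild-type vehicle male replicate 3. For lithium by genotype, 0 calls became 1 without heterozygous lithium male replicate 2. For fluoxetine in heterozygous males, 6726 calls became 4175 without heterozygous fluoxetine male replicate 3. For fluoxetine by genotype, 0 calls became 1277 without heterozygous fluoxetine male replicate 2, 64 without heterozygous fluoxetine male replicate 5 and 1226 without heterozygous vehicle male replicate 1. For heterozygous fluoxetine against wild-type vehicle, 3410 calls became 2009 without heterozygous fluoxetine male replicate 3, 2145 without heterozygous fluoxetine male replicate 4 and 2189 without wild-type vehicle female replicate 3. For genotype across drugs, 3823 calls became 2547 without heterozygous lithium male replicate 1. For fluoxetine across genotypes, 553 calls became 1020 without heterozygous fluoxetine male replicate 1, 896 without heterozygous fluoxetine male replicate 2, 1316 without heterozygous fluoxetine male replicate 5 and 358 without wild-type fluoxetine male replicate 4.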

Other observations

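The comparisons across genotypes were chosen after the results were seen, and so were the genes named from them. With lithium in both genotypes 207 genes were higher and 173 lower, and those of smallest p included the nucleolar gene Rbm28 (0.22 ± 0.03), Zbtb16 (0.54 ± 0.07), Wipf3 (0.33 ± 0.04) and Banp (0.32 ± 0.05), each higher than the vehicle mean of the same sex and genotype in 20 of 20 mice, with adjusted p values of 2.62e-06 to 2.44e-05 by limma. Ctnnb1 fell in 20 of 20 mice (-0.16 ± 0.03, limma adjusted p = 0.000937), and Gsk3b did not pass (0.01 ± 0.03, adjusted p = 0.898). Of 26 unfolded protein and integrated stress response genes 11 rose, 1 fell and 14 did not pass, with 18 higher and 1 lower adjusted over the list alone (adjusted p = 0.016 with an estimated correlation). Of 30 immediate early genes 0 rose, 12 fell and 18 did not pass, with 0 higher and 21 lower adjusted over the list alone (adjusted p = 0.016 with an estimated correlation).

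With fluoxetine in both genotypes 259 genes were higher and 294 lower. Stard4 fell in 18 of 19 mice (-0.39 ± 0.04, limma adjusted p = 4.38e-08), and the glial transcription factor Sox8 (-0.26 ± 0.03) and the lactate transporter Slc16a1 (-0.27 ± 0.04) fell too. Of 24 cholesterol biosynthesis genes 0 rose, 12 fell and 12 did not pass, with 0 higher and 20 lower adjusted over the list alone (adjusted p = 0.023 with an estimated correlation). Of 30 immediate early genes 0 rose, 14 fell and 16 did not pass, with 0 higher and 20 lower adjusted over the list alone (adjusted p = 0.027 with an estimated correlation). Of 23 interferon response genes 8 rose, 0 fell and 15 did not pass, with 12 higher and 0 lower adjusted over the list alone (adjusted p = 0.46 with an estimated correlation). Wild-type fluoxetine female replicate 1 had a list mean 1.093 above that of all libraries. The other wild-type fluoxetine mice lay from -0.192 to 0.204. Heterozygous fluoxetine male replicates 2 and 3 lay at 0.955 and 0.647, and the other heterozygous fluoxetine mice from -0.27 to 0.464.

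Ndn under vehicle was at 4603, 3729, 2391, 2551 and 2559 normalised counts in heterozygous females, and at 3837, 4303, 4759, 3883 and 5117 in wild-type females.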
